A study of Homo sapiens with 6 samples.

How the data were processed

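Total RNA of 3 human cell lines was measured on 6 short-oligonucleotide expression arrays, 2 per line. The lines were PC-3, a prostate cancer line derived from a bone metastasis, and TEM4-18 and TEM2-5, which per the labels were isolated in separate experiments from PC-3 cells that had crossed a layer of human lung microvascular endothelial cells. Per the labels' protocols, the cells grew in the same serum-containing medium and RNA was extracted with TRIzol and column cleanup. The titles number the arrays of each line as replicates 1 and 2. The source name of the second TEM2-5 array says replicate 1, and its title was followed. The labels do not say that the 2 arrays of a line came from separate cultures. P-values of single probe sets and genes therefore measure the spread between these arrays, which may be technical. Those of the main list test set a list's genes against other genes, and shuffles and bootstrap intervals take genes as units. None of these measures the spread between cultures or isolates. Differences between lines rest on the single PC-3 line and 1 isolate for each TEM line.

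The values deposited by the authors are linear signal intensities for each probe set, made with MAS5 per the submitters' processing notes, which give no version. The 2% trimmed mean lay between 1500.17 and 1500.18 on the 6 arrays, so the deposited intensities were taken as scaled between arrays and were not normalized again. Detection calls and scans were not used here. The array holds 54675 probe sets, of which 62 were controls. The platform annotation gave 41097 probe sets a single gene symbol, 1801 several and 11777 none. No gene was named from a probe set with several. Symbols were matched by gene ID to a RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols and left 54 probe sets unmatched. That table was used only for names and for which genes neighbour each other. The labels name no build, and no coordinates are given.

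Intensities were transformed to log2(value + 51.8), where 51.8 is the 20th percentile of all deposited values. Probe sets were kept where the mean over the 6 arrays exceeded 174, the 40th percentile, which left 32768 probe sets and 13621 genes. Each gene was represented by its brightest single-symbol probe set, which can miss transcripts that other probe sets detect. Probe set names that end in _s_at or _x_at mark probes that can match several transcripts or related genes. A fold change on the log2(value + 51.8) scale understates the change of genes with low signals. MAS5 subtracts mismatch signals, and its low values are noisy. The number of arrays, rather than a read depth, limits the precision here.

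Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) to all 6 arrays, with 3 group means and 3 residual degrees of freedom. The median residual SD was 0.17 on the log2 scale. The 4 contrasts were TEM4-18 against PC-3, TEM2-5 against PC-3, the mean of both TEM lines against PC-3, and TEM4-18 against TEM2-5. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested probe sets of a contrast and a threshold of 0.05. Errors of log2 fold changes are standard errors of the fit, and errors of signals are SDs over 2 arrays. Groups of 2 arrays are too small for a permutation test of a single gene or for counts over other splits of the arrays.

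The 24 gene lists were written from textbook knowledge before the data were examined, as were the contrasts, the rule for named genes and the alternatives. The lists covered epithelial junctions, the epithelial program, keratins, transcription factors of the epithelial-mesenchymal transition (EMT), mesenchymal genes, basement membrane, integrins, adhesion to endothelium, proteases, cytokines, interferon-stimulated genes, antigen presentation, TGF-beta and BMP, WNT and Notch, receptor tyrosine kinases, cell cycle, hypoxia and glycolysis, cholesterol synthesis, stress responses, prostate lineage, neural genes, and markers of endothelial cells, fibroblasts and leukocytes. The EMT-related lists and the genes always named were chosen in knowledge of published interest in these lines and are not independent evidence of a direction. Some genes sit in more than 1 list. Lists were tested with limma's camera, which compares a list with all other tested genes, at a preset correlation of 0.01 and with adjustment over the 24 lists of a contrast. With an estimated correlation, camera called 0 lists in each of the 4 contrasts, while 5, 4, 5 and 5 had an unadjusted p under 0.05 and fry called 18, 13, 18 and 6. The adjusted p with an estimated correlation is given beside each called list. The rotation test fry, which asks only whether a list's genes move one way on balance, was an alternative.

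Named genes followed a fixed rule. A set of 12 genes was always named. For both lines, the 10 rising and 10 falling genes with the largest smaller change were taken among genes past the threshold in both, where every TEM array lay beyond both PC-3 arrays. For each line, 5 each way were taken by log2 fold change among genes past the threshold whose groups of arrays did not overlap, for the contrast of the 2 lines 8 each way, and for each list up to 2 members each way on the mean contrast and 1 each way between the lines. XIST, TSIX and Y-linked genes were left out, and some genes of the lists were not analysed here. Alternatives changed the pseudocount, the filter, the normalization, the variance model, the arrays in the fit, the replicate block, the probe set per gene, the list test and the minimum fold, and left out each array in turn.

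The steps were tested on simulated data drawn from the PC-3 means and moderated residual SDs of the 32768 probe sets, for TEM4-18 against PC-3. Of 50 probe sets changed at each size, limma recovered 18% at 1.5-fold, 54% at 2-fold, 84% at 4-fold and 96% at 8-fold, with 10 false calls among 136. Camera at the preset correlation gave a p under 0.05 for 4 of 200 random lists of 30 probe sets, and for 50 of 50 such lists shifted by 0.5 on the log2 scale. The simulated probe sets varied independently of each other. This check therefore does not show the rate of false calls for lists whose genes vary together. The estimated correlation was 0.261 for interferon-stimulated genes, for example. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.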

Results

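Gene expression was compared between PC-3 prostate cancer cells and 2 lines isolated from them after migration across an endothelial cell layer, TEM4-18 and TEM2-5. Each line was measured on 2 arrays. Median signals lay between 267 and 317 in array units, and the 95th percentile between 10049 and 10349. The ratio of 3' to 5' probe sets was 1.14 to 1.22 for ACTB and 0.923 to 0.986 for GAPDH, and the PC-3 range overlapped that of both TEM lines for each ratio. Across the tested probe sets, log2 signals of arrays of the same line correlated at 0.976 for PC-3, 0.979 for TEM4-18 and 0.980 for TEM2-5. Correlations across probe sets were 0.923 to 0.926 between PC-3 and TEM4-18, 0.951 to 0.954 between PC-3 and TEM2-5, and 0.968 to 0.972 between the TEM lines. Probe sets are not independent replicates. The first principal component held 58.8% of the variance and placed TEM2-5, at 12.5 and 13.9, between PC-3, at -69.4 and -71.0, and TEM4-18, at 56.1 and 58.0.

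The first comparison asked which genes differed between PC-3 cells and TEM4-18, the line isolated in the first experiment. TEM4-18 had lost nearly all signal of CDH1, which encodes E-cadherin, the adhesion molecule of epithelial adherens junctions: 14772 ± 531 in PC-3 and 41.8 ± 22.7 in TEM4-18 (SD, n = 2), a log2 fold change of -7.33 ± 0.17 (SE, adjusted p = 1.17e-09). ESRP1, an epithelial splicing regulator, fell from 13535 ± 1071 to 28.1 ± 8.76 (log2 fold change -7.41 ± 0.15), and EPCAM, an epithelial surface glycoprotein, from 43452 ± 1641 to 1880.3 ± 219 (log2 fold change -4.50 ± 0.09). ZEB1, a transcriptional repressor of epithelial genes, rose from 1842 ± 24.8 to 6970.1 ± 147, a log2 fold change of 1.89 ± 0.10 (adjusted p = 3.87e-07). All 38 tested genes of the epithelial program fell, with a median log2 fold change of -2.88 (adjusted p = 2.88e-33, and adjusted p = 0.0682 with an estimated correlation). The mean CDH1 and ESRP1 signals in TEM4-18 lay below the pseudocount of 51.8, so these fold changes understate the difference.

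By the fixed rule, the genes past the threshold with the largest falls in TEM4-18 were CALB1, which encodes the calcium-binding protein calbindin (-7.96 on the log2 scale), ESRP1, CDH1, the epithelial transcription factor EHF (-6.82) and DNAJC15 (-6.78). The largest rises were those of LGR5, a receptor for R-spondins that marks epithelial stem cells in several tissues (4.53), FAM107A (3.94), the lectin-like gene CLEC2B (3.79), the cysteine protease inhibitor CST1 (3.51) and the teneurin TENM1 (3.43). The order of the falls depends on the pseudocount, since the mean signals of EHF (19.9) and DNAJC15 (7.71) also lay below it in TEM4-18. With a pseudocount of 1, these falls were -9.55 for DNAJC15, -8.96 for EHF, -8.89 for ESRP1, -8.54 for CDH1 and -8.38 for CALB1. Some log2 values moved by over 1.5 times while the call held: with all probe sets averaged, EHF was at -3.83 and DNAJC15 at -2.998. ITGB4, the integrin subunit of hemidesmosomes, fell by 3.64 on the log2 scale.

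Of 30 tested junction genes, 21 fell and 2 rose in TEM4-18 (adjusted p = 1.03e-09, and adjusted p = 0.169 with an estimated correlation), with 22 lower and 2 higher when adjusted over the list alone. Of 34 cytokine and NF-kappaB responsive genes, 21 fell and 2 rose (adjusted p = 5.93e-09, and adjusted p = 0.181 with an estimated correlation), among them the neutrophil chemokine CXCL8 (-5.49) and the siderophore-binding LCN2 (-6.62). Of 39 interferon-stimulated genes, 26 fell and 1 rose (adjusted p = 4.96e-12, and adjusted p = 0.280 with an estimated correlation), with IFI27 at -4.76 and the RNA sensor IFIH1 at -3.22. Camera also called the prostate lineage list in this comparison, with 7 of 16 genes lower and 2 higher (adjusted p = 0.0445, and adjusted p = 0.513 with an estimated correlation), and antigen presentation, with 6 of 20 lower and 0 higher (adjusted p = 0.0269, and adjusted p = 0.279 with an estimated correlation). The other lists called lower were keratins (adjusted p = 0.00258, and adjusted p = 0.189 with an estimated correlation), receptor tyrosine kinases (adjusted p = 0.00694, and adjusted p = 0.189 with an estimated correlation), hypoxia and glycolysis (adjusted p = 0.00114, and adjusted p = 0.395 with an estimated correlation), cholesterol (adjusted p = 0.00148, and adjusted p = 0.395 with an estimated correlation) and stress (adjusted p = 0.00697, and adjusted p = 0.395 with an estimated correlation). List calls were lost for antigen presentation (median -0.36) without TEM4-18 replicate 2 (-0.27, adjusted p = 0.0554). For prostate lineage (median -0.53) with no filter on low values (-0.38, adjusted p = 0.0600), with a filter at the 60th percentile (-0.39, adjusted p = 0.0572), without PC-3 replicate 1 (-0.24, adjusted p = 0.203) and with all probe sets averaged (-0.23, adjusted p = 0.193), the call was lost. Other list medians moved by over 1.5 times while the call held: cholesterol (from -0.45 to -0.27 without PC-3 replicate 1 and -0.26 with all probe sets averaged) and keratins (from -1.02 to -0.45 with no filter on low values). Prostate lineage (from -0.53 to -0.89 without PC-3 replicate 2) and receptor tyrosine kinases (from -0.40 to -0.19 with no filter on low values) moved as well. Median, mean and test differed in sign for mesenchymal genes (0.069, -0.12 and up), basement membrane (0.048, -0.29 and down), TGF-beta and BMP (0.23, -0.11 and up), neural genes (0.078, -0.15 and up), endothelial markers (-0.085, 0.24 and up), fibroblast markers (-0.072, -0.14 and up) and leukocyte markers (0.053, -0.046 and up).

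Over all probe sets, 8396 of 32768 differed between TEM4-18 and PC-3, 4202 higher and 4194 lower. A change of at least 2-fold was seen in 2681 of them, 1143 higher and 1538 lower. By gene, 1805 were higher and 2183 lower, and at 2-fold or more 390 were higher and 794 lower. Of named genes called here with several tested probe sets, 21 of 64 had a probe set without the same call, and ZEB1 had the call on 3 of 4. Without the mean-variance trend, 5360 probe sets passed the threshold.

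**Figure D1:**
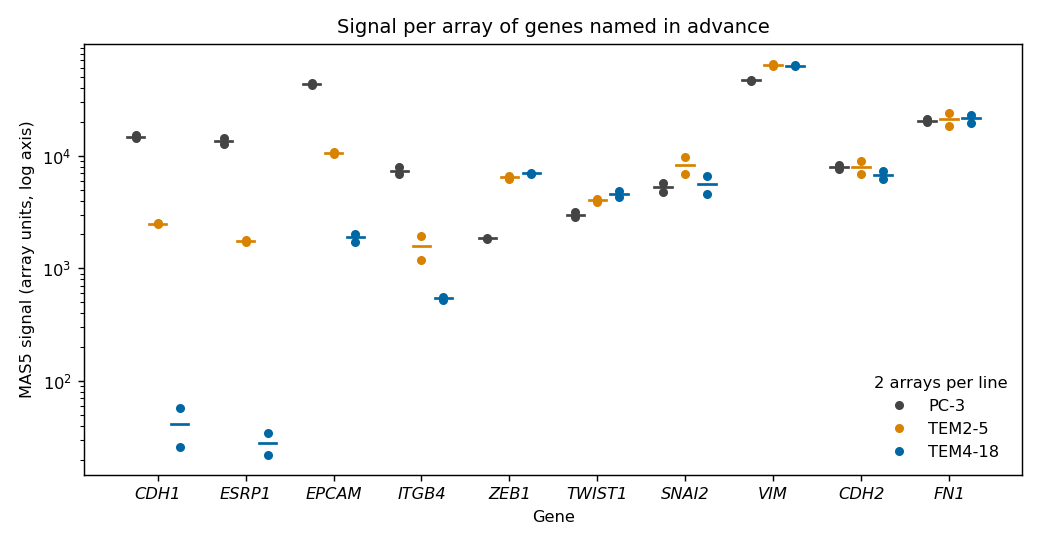
MAS5 signal in array units, on a log axis, of 10 genes named in advance on each of the 2 arrays of PC-3, TEM2-5 and TEM4-18 (points), with the mean of each line as a bar. CDH1 lay at 14772 in PC-3, 2499 in TEM2-5 and 41.8 in TEM4-18, while CDH2 and FN1 passed the threshold in no contrast.

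The second comparison asked the same question of TEM2-5, the line isolated when the migration experiment was repeated. The epithelial genes fell here too, to intermediate levels: CDH1 was 2499 ± 28.9 (SD, n = 2), a log2 fold change against PC-3 of -2.54 ± 0.17 (SE, adjusted p = 1.11e-05), ESRP1 was 1762 ± 58.6 (log2 fold change -2.90 ± 0.15) and EPCAM was 10626 ± 322 (log2 fold change -2.03 ± 0.09). ZEB1 rose to 6419 ± 247, a log2 fold change of 1.77 ± 0.10 (adjusted p = 2.51e-06). All 38 genes of the epithelial program fell, with a median of -1.87 (adjusted p = 3.62e-32, and adjusted p = 0.0717 with an estimated correlation). SNAI2, another EMT transcription factor, passed the threshold in TEM2-5 (0.64 ± 0.19, adjusted p = 0.0427) and not in TEM4-18 (0.08 ± 0.19, adjusted p = 0.797), and the difference between the lines did not pass either (adjusted p = 0.230).

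By the same rule, the largest falls in TEM2-5 on the log2(value + 51.8) scale were those of CDH3, the P-cadherin gene (-3.32), IFI27 (-3.18), C1orf116 (-3.16), the decoy interleukin-1 receptor IL1R2 (-3.13) and LSR, a component of tricellular junctions (-3.01). The largest rises were those of FAM107A (3.45), LGR5 (3.07), the GABA-B receptor subunit gene GABBR2 (3.00), the steroid dehydrogenase gene HSD17B2 (2.63) and SLC26A5-AS1 (2.62), an antisense transcript. The order of the falls depends on the pseudocount, since the mean TEM2-5 signals of CBLC (-3.01 on this scale) and LRRC75A (-2.97) lay below it. With a pseudocount of 1, the values were -4.55 for LRRC75A, -4.48 for CBLC, -3.45 for IL1R2, -3.42 for CDH3, -3.41 for IFI27, -3.23 for C1orf116 and -3.10 for LSR. Some log2 values moved by over 1.5 times while the call held: with all probe sets averaged, FAM107A was at 2.08. With a pseudocount of 1, LGR5 was at 4.74. With 4 times the pseudocount, LGR5 was at 1.89, so its place among the rises depends on the pseudocount too.

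Junction genes fell in 18 of 30 cases and rose in 2 (adjusted p = 1.29e-09, and adjusted p = 0.145 with an estimated correlation). Cytokine genes fell in 18 of 34 cases and rose in 2 (adjusted p = 2.85e-07, and adjusted p = 0.182 with an estimated correlation), and interferon-stimulated genes fell in 24 of 39 and rose in 1 (adjusted p = 2.6e-10, and adjusted p = 0.292 with an estimated correlation). The list of fibroblast markers was called higher in TEM2-5, with 4 of 12 members higher and 0 lower (adjusted p = 0.0161, and adjusted p = 0.283 with an estimated correlation). The median signal over all 20 markers was 250.3 and 312 on the TEM2-5 arrays, and 208 and 185 on the PC-3 arrays. Mesenchymal genes rose in 16 of 41 cases and fell in 4 (adjusted p = 0.00263, and adjusted p = 0.392 with an estimated correlation). Also called were EMT transcription factors, upward (adjusted p = 0.00869, and adjusted p = 0.283 with an estimated correlation), and, downward, keratins (adjusted p = 2.9e-05, and adjusted p = 0.145 with an estimated correlation), hypoxia and glycolysis (adjusted p = 0.00117, and adjusted p = 0.402 with an estimated correlation) and cholesterol (adjusted p = 0.00124, and adjusted p = 0.402 with an estimated correlation). List calls were lost for EMT transcription factors (median 0.13) with no filter on low values (-0.0078, adjusted p = 0.128). For fibroblast markers (median 0.48) with no filter on low values (0.13, adjusted p = 0.136), the call was lost. Other list medians moved by over 1.5 times while the call held: cholesterol (from -0.35 to -0.22 without PC-3 replicate 1) and EMT transcription factors (from 0.13 to 0.42 with a filter at the 60th percentile, 0.20 after quantile normalization, 0.38 without PC-3 replicate 1, 0.38 without TEM2-5 replicate 2 and 0.23 with all probe sets averaged). Fibroblast markers (from 0.48 to 0.31 with 4 times the pseudocount and 1.03 with a filter at the 60th percentile) and hypoxia and glycolysis (from -0.15 to -0.075 without PC-3 replicate 1) moved as well. Keratins (to -0.61 with no filter on low values) and mesenchymal genes (from 0.24 to 0.063 with no filter on low values and 0.36 without TEM2-5 replicate 2) moved as well. Median, mean and test differed in sign for basement membrane (0.12, -0.025 and up) and endothelial markers (-0.0042, 0.16 and up).

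In all, 5325 probe sets differed between TEM2-5 and PC-3, 2838 higher and 2487 lower, and 1468 of them by at least 2-fold, 668 higher and 800 lower. By gene, more fell than rose: 1223 were higher and 1370 lower, and at 2-fold or more 236 and 435. Of named genes called here with several tested probe sets, 31 of 62 had a probe set without the same call, and the call was on 3 of 4 for ZEB1 and 1 of 2 for VIM. The count of probe sets depended on single arrays: it was 3323 without PC-3 replicate 2, 2968 without TEM2-5 replicate 1 and 2825 without TEM2-5 replicate 2. It was 2320 without the mean-variance trend.

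Both lines against the same PC-3 arrays shared 4727 probe sets past the threshold in the same direction, 2537 higher and 2190 lower, and 4 were called in opposite directions. By gene, 1091 were higher in both lines and 1239 lower. By the fixed rule, which ranks the smaller of the 2 changes on the log2(value + 51.8) scale, the 10 genes with the largest falls common to both lines were CDH3, IFI27, C1orf116, IL1R2, LSR, CBLC, LNCAROD, ALPP, LCN2 and LRRC75A. Their order depends on the pseudocount, since the mean signals of CBLC and LRRC75A lay below it in both TEM lines and those of CDH3, IL1R2 and ALPP in TEM4-18. With a pseudocount of 1, LRRC75A was at -4.96 in TEM4-18 and -4.55 in TEM2-5, CBLC at -4.49 and -4.48, and CDH3 at -8.13 and -3.42. LSR went from 6643 in PC-3 to 177 in TEM4-18 and 806 in TEM2-5. ALPP, placental alkaline phosphatase, has close relatives in the genome, and its probe set may read them. The 10 with the largest rises were FAM107A, LGR5, GABBR2, HSD17B2, SLC26A5-AS1, PELI2, CST1, CLEC2B, TAGLN3 and DGKG. The place of LGR5 among them depends on the pseudocount as well. GABBR2 went from 1529 to 16539.7 in TEM4-18 and 12605 in TEM2-5, and TAGLN3, a gene of neuronal cells, from 719 to 5972 and 4003.

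Independent lists of these sizes would share 364 higher and 318 lower probe sets. In 20 simulations of unchanged lines against the same PC-3 arrays, the mean number shared was 0.05 and the highest was 1. With no probe set changed, few calls are made at all. This count therefore cannot tell how many shared calls the common controls add when each line has many changes. The log2 fold changes of the 2 comparisons correlated at 0.845 across probe sets, against 0.50 in the simulations. Their covariance was 0.310 against a simulated 0.0347, a difference of 0.276. A split of the controls would leave 1 PC-3 array for each comparison and was not made, so part of the excess over independent lists may come from the shared controls. Of the shared probe sets, 3735 had the larger change in TEM4-18. The shared count was 3068 without PC-3 replicate 2, 2772 without TEM2-5 replicate 1, 2621 without TEM2-5 replicate 2 and 2131 without the mean-variance trend.

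**Figure D2:**
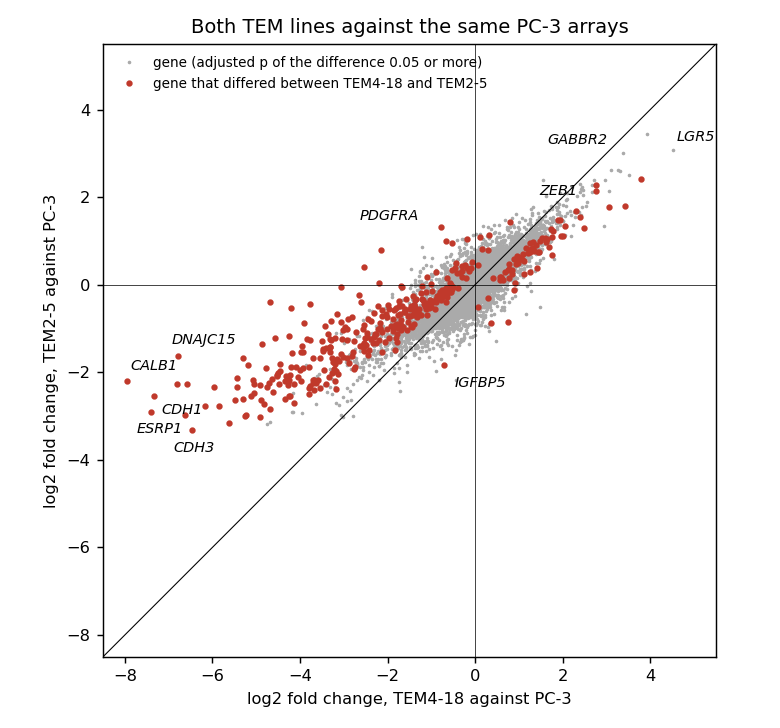
Log2 fold change of each of 13621 genes in TEM4-18 (x axis) and TEM2-5 (y axis) against the same 2 PC-3 arrays, with the line of equal change; red points are the 375 genes that differed between the TEM lines. CDH1 lies at -7.33 and -2.54, and PDGFRA at -0.77 and 1.32.

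The third comparison set the mean of both TEM lines against PC-3, and so described the average change of the isolated lines. Of 4083 genes called on it, 2330 passed in both lines in the same direction, 1480 in a single line and 273 in neither alone. Epithelial genes fell as a group, and 4 of 11 tested EMT transcription factors rose: ZEB1 by 1.83 ± 0.08 on the log2 scale (SE), TWIST2 by 1.64 ± 0.13 and TWIST1 by 0.52 ± 0.10. TCF4, named after its values were seen, was the fourth, and none fell (adjusted p = 0.0326, and adjusted p = 0.349 with an estimated correlation). ZEB2 and SNAI1 lay below the filter and were not tested, with signals of 94.6 to 164 and 35.4 to 306 over the 6 arrays. VIM, the intermediate filament of mesenchymal cells, rose by 0.45 ± 0.05 from a PC-3 signal of 46535. CDH2, the N-cadherin gene, and fibronectin FN1 did not pass, with log2 fold changes of -0.13 ± 0.11 (adjusted p = 0.470) and 0.04 ± 0.10 (adjusted p = 0.809). Adjusted over the list alone, the counts were 0 lower and 4 higher for EMT transcription factors.

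All 38 genes of the epithelial program fell on this contrast (median -2.44, adjusted p = 3.42e-32, and adjusted p = 0.0716 with an estimated correlation), and all 38 fell when adjusted over the list alone. Of the junction genes 21 of 30 fell (adjusted p = 1.14e-09, and adjusted p = 0.170 with an estimated correlation), while the desmosomal genes DSC3 (1.02 in TEM4-18 and 0.63 in TEM2-5) and PKP1 (0.71 in TEM4-18 and 0.63 in TEM2-5) rose. Keratins fell in 7 of 9 cases and rose in 0 (adjusted p = 0.000749, and adjusted p = 0.177 with an estimated correlation), with KRT7 (-2.30 in TEM4-18 and -1.88 in TEM2-5) and KRT4 (-2.14 in TEM4-18 and -1.70 in TEM2-5) as examples. The counts adjusted over the list alone were 23 lower and 3 higher for junctions and 7 lower and 1 higher for keratins.

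**Figure D3:**
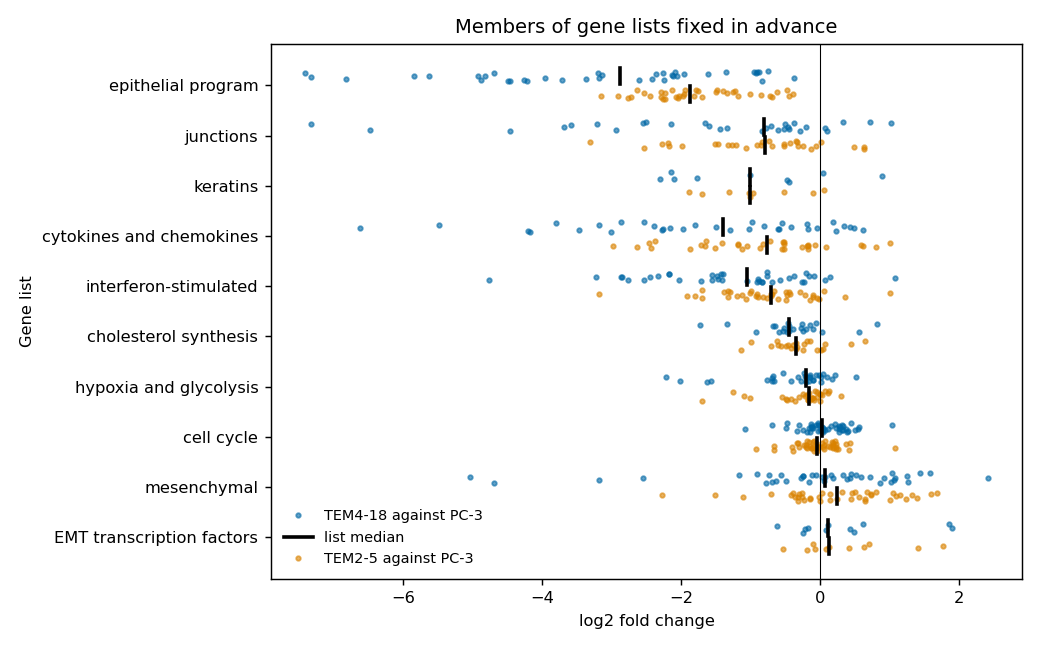
Log2 fold changes against PC-3 of the members of 10 gene lists fixed in advance, in TEM4-18 (blue) and TEM2-5 (orange), with list medians as black bars and points spread vertically for legibility. The epithelial program has medians of -2.88 and -1.87, and the cell cycle 0.03 and -0.05.

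Mesenchymal genes moved both ways, with 16 of 41 higher and 8 lower (adjusted p = 0.0356, and adjusted p = 0.462 with an estimated correlation). The matrix gene SPARC rose by 2.00 ± 0.49 on this contrast, although it did not pass in TEM2-5 alone (adjusted p = 0.0866), and the fibrillin gene FBN1 by 1.63 ± 0.14, whereas THBS1, thrombospondin, fell (-3.66 ± 0.13). The cytochrome gene CYP1B1 was lower on average (-2.54 ± 0.26), from -4.69 in TEM4-18 and -0.39 in TEM2-5, where it did not pass (adjusted p = 0.435). Fibroblast markers rose in 3 of 12 cases and fell in 1, with COL1A1 at 1.41 and COL6A3 at 1.24 against lumican, LUM, at -2.15, which did not pass in TEM2-5 alone (-1.11, adjusted p = 0.138; adjusted p = 0.120 for the list). Basement membrane genes passed in few cases, 5 lower and 1 higher of 25 (adjusted p = 0.715). The median of that list was 0.07, its mean -0.16 and the direction of the test up. COL4A1 rose (0.47) and COL4A6 fell (-1.22). Integrins were lower in 5 of 17 cases and higher in 2 (adjusted p = 0.361), with ITGB4 (-2.94) and ITGB8 (-2.36) lower and the collagen-binding ITGA1 (1.63) and fibronectin-binding ITGA5 (0.60) higher. Adjusted over the list alone, the counts were 9 lower and 17 higher for mesenchymal genes, 1 lower and 3 higher for fibroblast markers, 5 lower and 2 higher for basement membrane and 6 lower and 3 higher for integrins.

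Genes for adhesion to endothelium fell in 14 of 40 cases and rose in 9 (adjusted p = 0.233). The selectin ligand carrier CD24 (-2.68) and L1CAM (-2.15; TEM2-5 alone -1.32, adjusted p = 0.125) fell, and the chemokine receptor ACKR3 (1.56) and CD99L2 (1.06) rose. Proteases and their inhibitors fell in 10 of 39 cases and rose in 4 (adjusted p = 0.0631), with the kallikreins KLK5 (-3.48) and KLK6 (-2.95) lower and ADAM12 (1.89) and MMP16 (1.05) higher. The counts adjusted over the list alone were 15 lower and 9 higher for adhesion to endothelium and 11 lower and 4 higher for proteases.

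Inflammatory genes were lower on average. Cytokine genes fell in 21 of 34 cases and rose in 2 (adjusted p = 2.66e-08, and adjusted p = 0.177 with an estimated correlation), with LCN2 (-4.80) and CXCL8 (-4.07) at the low end and IL6R (0.62) and IL11 (0.62) higher. IL11 passed in TEM2-5 (1.00, adjusted p = 0.00836) and not in TEM4-18 (0.23, adjusted p = 0.464), and its call on the mean was lost, with a value of -0.0069, when all its probe sets were averaged. Interferon-stimulated genes fell in 27 of 39 cases and rose in 1 (adjusted p = 1.6e-11, and adjusted p = 0.322 with an estimated correlation), with 29 lower and 1 higher when adjusted over the list alone. IFI27 was at -3.97, IFIH1 at -2.57 and the guanylate-binding GBP2, the member that rose, at 1.04. Antigen presentation genes fell in 4 of 20 cases and rose in 1 (adjusted p = 0.0529). HLA-B (-1.11) and HLA-C (-1.02) fell, on probe sets that can match related genes, as do those of CD24, CXCL8 and KRT8. TAPBP rose (0.30). Adjusted over the list alone, the counts were 22 lower and 4 higher for cytokines and 6 lower and 1 higher for antigen presentation.

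Receptor tyrosine kinases and growth factors fell in 19 of 47 cases and rose in 4 (adjusted p = 0.0219, and adjusted p = 0.230 with an estimated correlation), with the binding protein gene IGFBP2 (-3.89) and the EGF receptor ligand TGFA (-3.12) lower and FGFR1 (0.63) and IGFBP3 (0.51) higher. TGF-beta and BMP genes went both ways, 11 of 45 lower and 14 higher (adjusted p = 0.378). The latent TGF-beta binding protein LTBP1 rose (1.53), as did the BMP-responsive ID3 (1.39), and GDF15 (-2.14) and PMEPA1 (-1.96) fell. The list's median was 0.23 and its mean -0.03, with the test upward. WNT and Notch genes fell in 12 of 39 cases and rose in 9 (adjusted p = 0.388), with LGR5 (3.80) and the Notch-responsive HEY1 (1.12) higher and NOTCH3 (-2.70) and WNT9A (-2.38) lower. The counts adjusted over the list alone were 20 lower and 4 higher for receptor tyrosine kinases, 12 lower and 16 higher for TGF-beta and BMP and 12 lower and 9 higher for WNT and Notch.

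Hypoxia and glycolysis genes fell in 12 of 32 cases and rose in 1 (adjusted p = 0.000749, and adjusted p = 0.386 with an estimated correlation), with adrenomedullin, ADM, at -1.96 and DDIT4 at -1.51, and ENO2 higher at 0.40. Cholesterol genes fell in 12 of 23 cases and rose in 1 (adjusted p = 0.000986, and adjusted p = 0.386 with an estimated correlation), with the regulator SREBF1 at -1.44, the synthase HMGCS1 at -1.16 and STARD4 higher at 0.73. Stress genes fell in 13 of 37 cases and rose in 5 (adjusted p = 0.0398, and adjusted p = 0.462 with an estimated correlation), with ATF3 at -3.03 and ATF6 and the metallothionein MT1F higher at 0.70 and 0.62. Cell cycle genes were called in 7 cases as lower and 10 as higher of 48 (adjusted p = 0.433), with a list median of -0.01, a mean of 0.01 and an upward test. The CDK inhibitor genes CDKN2B (1.05) and CDKN2A (0.48) rose, and the cyclin gene CCNE1 (-1.09 in TEM4-18 and -0.92 in TEM2-5) and the replication licensing gene CDT1 (-0.57) fell. Adjusted over the list alone, the counts were 14 lower and 1 higher for hypoxia and glycolysis, 14 lower and 1 higher for cholesterol, 16 lower and 5 higher for stress and 9 lower and 14 higher for the cell cycle.

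Prostate lineage genes fell in 7 of 16 cases and rose in 3 (adjusted p = 0.0602), with GATA2 (-2.90) and TRIM29 (-2.02) lower and TMPRSS2 (1.61) and HOXB13 (0.56) higher. Neural and neuroendocrine genes fell in 4 of 15 cases and rose in 3 (adjusted p = 0.408, median 0.11, mean -0.05, test upward), with DPYSL3 (1.03) and STMN3 (0.76) higher and MAP2 lower (-1.28). Endothelial markers rose in 4 of 15 tested cases and fell in 1 (adjusted p = 0.378, median -0.10, mean 0.20, test upward). The VEGF receptor gene KDR rose by 2.35 ± 0.28 and the endoglin gene ENG by 1.22 ± 0.25, and ESAM and ROBO4, named after their values were seen, were the others. S1PR1 fell (-1.12). Leukocyte markers rose in 1 of 8 tested cases, HCLS1 (0.59), and fell in 0 (adjusted p = 0.408). HCLS1 rose in TEM2-5 (1.08, adjusted p = 0.00151) and was at 0.11 in TEM4-18 (adjusted p = 0.694). The median signals of the 3 marker lists lay between percentiles 35.2 and 41.7 of all probe sets. The counts adjusted over the list alone were 8 lower and 3 higher for prostate lineage, 4 lower and 3 higher for neural genes, 1 lower and 4 higher for endothelial markers and 1 lower and 3 higher for leukocyte markers.

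On this contrast 8639 probe sets passed the threshold, 4421 higher and 4218 lower, and 2136 of them changed by at least 2-fold, 948 higher and 1188 lower. By gene, 1879 were higher and 2204 lower, and at 2-fold or more 324 and 636. For 177 of these probe sets the TEM and PC-3 arrays overlapped. Without the mean-variance trend the count was 5461. List calls were lost for EMT transcription factors (median 0.12) with no filter on low values (-0.0052, adjusted p = 0.153) and without PC-3 replicate 2 (0.39, adjusted p = 0.0526). For mesenchymal genes (median 0.13) with no filter on low values (0.0027, adjusted p = 0.0735), without PC-3 replicate 1 (0.086, adjusted p = 0.0572), without TEM4-18 replicate 2 (0.13, adjusted p = 0.0574) and with all probe sets averaged (0.14, adjusted p = 0.0542), the call was lost. For stress (median -0.20) after quantile normalization (-0.20, adjusted p = 0.0545), without PC-3 replicate 1 (-0.12, adjusted p = 0.192), without TEM4-18 replicate 2 (-0.18, adjusted p = 0.0574), without TEM2-5 replicate 2 (-0.12, adjusted p = 0.0647) and with all probe sets averaged (-0.12, adjusted p = 0.0650), the call was lost. Other list medians moved by over 1.5 times while the call held: cholesterol (from -0.36 to -0.23 with all probe sets averaged) and EMT transcription factors (from 0.12 to 0.36 with a filter at the 60th percentile, 0.20 after quantile normalization, 0.23 without PC-3 replicate 1, 0.23 without TEM4-18 replicate 2 and 0.24 without TEM2-5 replicate 2). Hypoxia and glycolysis (from -0.17 to -0.11 without PC-3 replicate 1 and -0.26 without PC-3 replicate 2) and keratins (from -0.99 to -0.48 with no filter on low values) moved as well. Receptor tyrosine kinases (from -0.20 to -0.39 with a filter at the 60th percentile) moved as well.

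Named genes called on the mean that did not pass in TEM2-5 alone also included ENO2 (0.29, adjusted p = 0.0954), ID3 (1.14, adjusted p = 0.0890), MAP2 (-1.07, adjusted p = 0.129), S1PR1 (-0.93, adjusted p = 0.0974) and STARD4 (0.65, adjusted p = 0.0683). CDT1 (-0.48 in TEM4-18 and -0.66 in TEM2-5, adjusted p = 0.127 and 0.0553) and TAPBP (0.28 and 0.32, adjusted p = 0.0880 and 0.0749) passed in neither line alone. Some log2 values moved by over 1.5 times while the call held: with all probe sets averaged, FAM107A was at 2.45, PKP1 at 0.30, KRT7 at -1.21, ATF6 at 0.44, ATF3 at -1.49, HOXB13 at 0.98, GATA2 at -1.26 and COL1A1 at 0.66. With a pseudocount of 1, LRRC75A was at -4.75, SPARC at 3.29 and LUM at -3.39. With 4 times the pseudocount, DGKG was at 1.46, CBLC at -1.74, LRRC75A at -1.69, KRT4 at -1.17, SPARC at 1.14, MAP2 at -0.80 and LUM at -1.32. Without PC-3 replicate 1, IGFBP3 was at 0.30 and CDT1 at -0.91.

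Of named genes called on this contrast with several tested probe sets, 23 of 66 had a probe set without the same call. They were, with the number of probe sets that had it, ADAM12 (2 of 4), ATF3 (2 of 3), ATF6 (2 of 4), CD99L2 (3 of 4), CDKN2B (1 of 2), CDT1 (1 of 2), COL1A1 (4 of 5), COL4A1 (1 of 2), COL4A6 (1 of 3), DNAJC15 (2 of 3), FGFR1 (4 of 7), GATA2 (2 of 3), GBP2 (1 of 2), IGFBP5 (5 of 6), IL11 (1 of 2), IL6R (2 of 3), ITGB8 (1 of 2), KRT7 (2 of 3), MAP2 (1 of 2), MMP16 (1 of 5), PKP1 (1 of 2), STMN3 (1 of 2) and TAPBP (1 of 3). With all probe sets of a gene averaged, the calls of CDT1 (-0.45, adjusted p = 0.0529), MMP16 (0.62, adjusted p = 0.0542), STMN3 (0.53, adjusted p = 0.103) and TAPBP (0.34, adjusted p = 0.0742) were lost. Without the mean-variance trend, those of CDKN2A (adjusted p = 0.0916), CDT1 (adjusted p = 0.170), FGFR1 (adjusted p = 0.0625), HOXB13 (adjusted p = 0.0517), ID3 (adjusted p = 0.130), IGFBP3 (adjusted p = 0.0830), IL11 (adjusted p = 0.0822), L1CAM (adjusted p = 0.0632), S1PR1 (adjusted p = 0.0733), SPARC (adjusted p = 0.0759), SREBF1 (adjusted p = 0.0606), STARD4 (adjusted p = 0.110) and TAPBP (adjusted p = 0.155) did not pass. Changes of the filter or the normalization also ended calls, those of CDT1, ID3, IL11, MAP2, S1PR1 and TAPBP.

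Some calls on this contrast were lost with a single array left out, with these log2 values: without PC-3 replicate 1 those of ENO2 (0.39), FGFR1 (0.57), HCLS1 (0.43), ID3 (0.73), IL11 (0.68), KRT4 (-1.80), MAP2 (-1.10), S1PR1 (-1.22) and TAPBP (0.28). Without PC-3 replicate 2, those of CDKN2A (0.40), CDT1 (-0.24), GBP2 (0.76), IL11 (0.55), KRT4 (-2.04), L1CAM (-1.98), LUM (-1.83), MAP2 (-1.45), S1PR1 (-1.03), SPARC (1.11), STARD4 (0.41) and TAPBP (0.32) were lost. Without TEM2-5 replicate 1, those of CDT1 (-0.48), IL11 (0.64) and TAPBP (0.24) were lost. Without TEM2-5 replicate 2, those of IL11 (0.59) and MAP2 (-1.10) were lost. Without TEM4-18 replicate 1, those of CDT1 (-0.50), IL11 (0.48) and TAPBP (0.25) were lost.

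The fourth comparison tested whether the 2 TEM lines differed from each other. TEM4-18 had less signal than TEM2-5 for most genes that differed, and these included many of the epithelial genes: CDH1 differed by -4.79 ± 0.17 on the log2 scale (SE, adjusted p = 1.13e-07), ESRP1 by -4.51 ± 0.15 and EPCAM by -2.47 ± 0.09. ZEB1 differed by 0.12 ± 0.10, which did not pass (adjusted p = 0.700). Of the 38 epithelial program genes, 23 were lower in TEM4-18 and 0 higher (adjusted p = 6.07e-36, and adjusted p = 0.0608 with an estimated correlation). PDGFRA, a growth factor receptor of fibroblasts, changed in opposite directions against PC-3 (-0.77 ± 0.22 in TEM4-18 and 1.32 ± 0.22 in TEM2-5, adjusted p = 0.0265 and 0.00263), with a difference between the lines of -2.10 ± 0.22 (adjusted p = 0.000661). The PDGFRA call was carried by 1 of 2 tested probe sets in TEM4-18 against PC-3 and by 1 of 2 between the lines, and the call between the lines was lost without the mean-variance trend.

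Among genes past the threshold, those furthest below TEM2-5 in TEM4-18 on the log2(value + 51.8) scale were CALB1 (-5.77), DNAJC15 (-5.14), CDH1, EHF (-4.56), ESRP1, the elastase inhibitor PI3 (-4.32), CYP1B1 (-4.30) and the alarmin IL33 (-3.68). CYP1B1 and IL33 did not pass in TEM2-5 against PC-3 (-0.39 and -0.52). In TEM4-18, the mean signals of DNAJC15 (7.71), CYP1B1 (19.2), IL33 (19.8), EHF (19.9), ESRP1 and CDH1 lay below the pseudocount, so the order depends on it. A pseudocount of 1 gave -7.89 for DNAJC15, -6.66 for EHF, -6.51 for CYP1B1 and -6.19 for CALB1. Some log2 values moved by over 1.5 times while the call held: with all probe sets averaged, DNAJC15 was at -2.52, EHF at -1.89, IFIT2 at -2.26 and GATA2 at -1.51. With a pseudocount of 1, DNAJC15 was at -7.89 and CYP1B1 at -6.51. With 4 times the pseudocount, DNAJC15 was at -3.39, EHF at -3.004, CYP1B1 at -2.76 and IL33 at -2.25. Those furthest above among genes past the threshold were TENM1 (1.63), CCDC157 (1.62), CLEC2B (1.37), SYT16 (1.28), TMEM95 (1.25), FGF13 (1.20), IGFBP5 (1.13) and SERTAD4BP (1.07). LGR5 differed by 1.46 and did not pass (adjusted p = 0.106). IGFBP5 was below PC-3 in both lines, at 4011 and 1803 against 6589.8.

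Cytokine genes were lower in TEM4-18 in 11 of 34 cases and higher in 0 (adjusted p = 4.31e-10, and adjusted p = 0.146 with an estimated correlation). Interferon-stimulated genes were lower in 8 of 39 (adjusted p = 8.14e-10, and adjusted p = 0.315 with an estimated correlation) and junction genes in 8 of 30 (adjusted p = 2.11e-08, and adjusted p = 0.146 with an estimated correlation). Also called lower were receptor tyrosine kinases (adjusted p = 0.00163, and adjusted p = 0.146 with an estimated correlation), stress (adjusted p = 0.000477, and adjusted p = 0.315 with an estimated correlation), antigen presentation (adjusted p = 0.00706, and adjusted p = 0.217 with an estimated correlation), proteases (adjusted p = 0.0139, and adjusted p = 0.452 with an estimated correlation), prostate lineage (adjusted p = 0.0139, and adjusted p = 0.451 with an estimated correlation), mesenchymal genes (adjusted p = 0.0210, and adjusted p = 0.451 with an estimated correlation) and basement membrane (adjusted p = 0.0210, and adjusted p = 0.451 with an estimated correlation). The cell cycle list was called higher in TEM4-18 (adjusted p = 0.000439, and adjusted p = 0.451 with an estimated correlation) with a median difference of 0.08, and 0 of its 48 genes passed in limma, 4 at an unadjusted p under 0.05. Of the 12 lists called between the lines, fry did not call the cell cycle (adjusted p = 0.249), basement membrane (0.140), proteases (0.123), mesenchymal genes (0.0908), stress (0.0749), interferon-stimulated genes (0.0621) or prostate lineage (0.0557). Of 584 probe sets that differed, 117 were higher in TEM4-18 and 467 lower, so 20% were higher. By gene, 67 were higher and 308 lower, and at 2-fold or more 12 probe sets were higher and 289 lower. The share of 20% was 2.40% without the mean-variance trend, 30.5% when only the 2 lines were fitted, 21.1% after quantile normalization, and 5.30% to 24.7% when each array was left out in turn. The count itself was 300.0 with no filter on low values, 125 without the trend, 321 without TEM4-18 replicate 2, 218 without TEM2-5 replicate 1 and 265 without TEM2-5 replicate 2. The median, mean and test differed in sign for integrins (0.0020, -0.12 and down) and TGF-beta and BMP (0.0023, -0.14 and down).

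List calls were lost for basement membrane (median -0.14) without TEM4-18 replicate 2 (-0.12, adjusted p = 0.121) and without TEM2-5 replicate 1 (-0.045, adjusted p = 0.140). For the cell cycle (median 0.079) without TEM4-18 replicate 2 (0.028, adjusted p = 0.122) and without TEM2-5 replicate 1 (0.024, adjusted p = 0.0962), the call was lost. For mesenchymal genes (median -0.11) with a filter at the 60th percentile (-0.063, adjusted p = 0.0734), without TEM4-18 replicate 1 (-0.079, adjusted p = 0.128) and without TEM2-5 replicate 2 (-0.072, adjusted p = 0.0846), the call was lost. For prostate lineage (median -0.12) with all probe sets averaged (-0.15, adjusted p = 0.0608), the call was lost. For proteases (median -0.075) without TEM4-18 replicate 2 (0.059, adjusted p = 0.158) and without TEM2-5 replicate 1 (-0.040, adjusted p = 0.137), the call was lost. Other list medians moved by over 1.5 times while the call held: antigen presentation (from -0.24 to -0.15 without TEM4-18 replicate 2 and -0.15 without TEM2-5 replicate 2) and basement membrane (from -0.14 to -0.27 without TEM2-5 replicate 2). The cell cycle (from 0.079 to 0.13 without TEM4-18 replicate 1 and 0.12 without TEM2-5 replicate 2) and cytokines (from -0.44 to -0.74 with a filter at the 60th percentile and -0.70 without TEM2-5 replicate 1) moved as well. Junctions (from -0.25 to -0.15 without TEM4-18 replicate 2) and prostate lineage (from -0.12 to -0.25 without TEM4-18 replicate 1 and -0.044 without TEM2-5 replicate 2) moved as well. Proteases (from -0.075 to -0.14 with a filter at the 60th percentile, -0.039 after quantile normalization, -0.18 without TEM4-18 replicate 1 and -0.17 without TEM2-5 replicate 2) and stress (from -0.13 to -0.21 without TEM2-5 replicate 2) moved as well.

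Of named genes called between the lines with several tested probe sets, 21 of 31 had a probe set without the same call: ATF3 (1 of 3), CCDC157 (1 of 2), CLEC2B (1 of 2), COL4A6 (1 of 3), DNAJC15 (2 of 3), EHF (3 of 6), GATA2 (1 of 3), HEY1 (1 of 2), HLA-B (2 of 3), HLA-C (3 of 4), IGFBP5 (2 of 6), ITGB4 (1 of 3), ITGB8 (1 of 2), NT5E (1 of 4), PDGFRA (1 of 2), SERPINB5 (1 of 2), SERTAD4BP (1 of 2), SYT16 (1 of 2), TGFA (2 of 3), THBS1 (4 of 7) and TRIM29 (1 of 2). With all probe sets of a gene averaged, the calls of ATF3 (-0.66, adjusted p = 0.213), CCDC157 (0.34, adjusted p = 0.658), NT5E (0.35, adjusted p = 0.315) and SERTAD4BP (0.95, adjusted p = 0.110) were lost. Without the mean-variance trend, those of ACKR3 (adjusted p = 0.210), ATF3 (adjusted p = 0.196), CCDC157 (adjusted p = 0.230), CLEC2B (adjusted p = 0.0505), FGF13 (adjusted p = 0.255), GDF15 (adjusted p = 0.141), HCLS1 (adjusted p = 0.129), HLA-B (adjusted p = 0.174), IFIT2 (adjusted p = 0.0999), IGFBP5 (adjusted p = 0.0638), IL33 (adjusted p = 0.0999), ITGB4 (adjusted p = 0.167), KRT75 (adjusted p = 0.194), KRT8 (adjusted p = 0.351), NOTCH3 (adjusted p = 0.141), NT5E (adjusted p = 0.298), PDGFRA (adjusted p = 0.0759), SERTAD4BP (adjusted p = 0.119), SYT16 (adjusted p = 0.0616), TENM1 (adjusted p = 0.238) and WNT5A (adjusted p = 0.302) did not pass. Changes of the pseudocount, filter, normalization, variance model or arrays fitted also ended calls, those of ACKR3, ATF3, CCDC157, FGF13, KRT8, NOTCH3, NT5E, SERTAD4BP, TENM1, TMEM95 and WNT5A.

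Some calls between the lines were lost with a single array left out, with these log2 values: without PC-3 replicate 1 those of KRT8 (-0.46) and NOTCH3 (-1.52). Without PC-3 replicate 2, those of KRT8 (-0.46), NOTCH3 (-1.52) and NT5E (0.46) were lost. Without TEM2-5 replicate 1, those of ACKR3 (0.81), CCDC157 (1.54), FGF13 (1.04), HCLS1 (-0.98), KRT8 (-0.43), NOTCH3 (-1.79), NT5E (0.43), SERTAD4BP (1.22), TENM1 (1.20), TMEM95 (1.17) and WNT5A (0.44) were lost. Without TEM2-5 replicate 2, those of ACKR3 (0.96), ATF3 (-0.99), CCDC157 (1.69), FGF13 (1.36), HCLS1 (-0.97), KRT75 (0.86), KRT8 (-0.49), NOTCH3 (-1.24), NT5E (0.49), SERTAD4BP (0.92), TMEM95 (1.32) and WNT5A (0.44) were lost. Without TEM4-18 replicate 1, those of ACKR3 (1.05), CCDC157 (1.51), FGF13 (1.48), KRT75 (0.80), NOTCH3 (-1.28), NT5E (0.37), SERTAD4BP (1.16), TENM1 (1.84), TMEM95 (1.18) and WNT5A (0.38) were lost. Without TEM4-18 replicate 2, those of ACKR3 (0.72), ATF3 (-1.07), CCDC157 (1.73), FGF13 (0.92), HCLS1 (-0.88), KRT8 (-0.32), NOTCH3 (-1.75), NT5E (0.55), SERTAD4BP (0.98), TENM1 (1.42), TMEM95 (1.31) and WNT5A (0.50) were lost.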

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

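All measures of the tests of a fixed share of PC-3 RNA, and the tests of array scaling and of endothelial RNA, were chosen after the results were seen; the test of the difference between the lines was planned.

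The lines TEM4-18 and TEM2-5 differed, by the test of the difference itself, in 12 gene lists. Median log2 differences (TEM4-18 minus TEM2-5) were -1.01 for the epithelial program, -0.45 for interferon-stimulated genes, -0.44 for cytokines, -0.25 for junctions and -0.24 for antigen presentation. They were -0.19 for receptor tyrosine kinases, -0.14 for basement membrane, -0.13 for stress, -0.12 for prostate lineage, -0.11 for mesenchymal genes, -0.075 for proteases and 0.079 for the cell cycle. Adjusted p with an estimated correlation lay between 0.0608 and 0.452 for these lists, and fry did not call 7 of the 12. Single arrays ended calls or moved medians by over 1.5 times: without TEM2-5 replicate 1 the medians were -0.045 for basement membrane (call lost), -0.040 for proteases (call lost), -0.70 for cytokines and 0.024 for the cell cycle (call lost). Without TEM2-5 replicate 2 the medians were -0.072 for mesenchymal genes (call lost), -0.27 for basement membrane, -0.17 for proteases, -0.15 for antigen presentation, 0.12 for the cell cycle, -0.21 for stress and -0.044 for prostate lineage. Without TEM4-18 replicate 1 the medians were -0.079 for mesenchymal genes (call lost), -0.18 for proteases, 0.13 for the cell cycle and -0.25 for prostate lineage. Without TEM4-18 replicate 2 the medians were -0.15 for junctions, -0.12 for basement membrane (call lost), 0.059 for proteases (call lost), -0.15 for antigen presentation and 0.028 for the cell cycle (call lost).

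Among named epithelial, adhesion, integrin and basement membrane genes, the log2 difference between the lines was -4.79 for CDH1, -4.51 for ESRP1, -4.56 for EHF, -3.16 for CDH3, -2.57 for CD24, -2.47 for C1orf116, -2.47 for EPCAM, -1.89 for LSR, -1.88 for ITGB8, -1.41 for ITGB4, -1.07 for COL4A6 and -0.46 for KRT8. Inflammatory and antigen presentation genes differed by -3.68 (IL33), -3.64 (LCN2), -2.85 (CXCL8), -1.48 (IFIT2), -1.31 (IFIH1), -0.76 (HLA-B) and -0.73 (HLA-C). Growth factor, signalling and stress genes differed by -3.53 (TGFA), -3.11 (IGFBP2), -2.77 (THBS1), -2.10 (PDGFRA), -1.79 (GDF15), -1.52 (NOTCH3), -1.28 (ATF3) and -0.64 (HEY1). Other lower genes were CALB1 (-5.77), DNAJC15 (-5.14), PI3 (-4.32), CYP1B1 (-4.30), GATA2 (-3.34), SERPINB5 (-2.59), LNCAROD (-2.26), ALPP (-2.26), TRIM29 (-1.99), KLK5 (-1.71), KLK6 (-1.17) and HCLS1 (-0.97). Higher in TEM4-18 were TENM1 (1.63), CCDC157 (1.62), CLEC2B (1.37), SYT16 (1.28), TMEM95 (1.25), FGF13 (1.20), IGFBP5 (1.13), SERTAD4BP (1.07), KRT75 (1.00), ACKR3 (0.88), NT5E (0.46) and WNT5A (0.44). All 12 of these higher calls were lost in 1 or more alternative runs, and CCDC157 was at 0.34 with all its probe sets averaged. Of 34 named calls between the lines that were run in the alternatives, 12 held in every run, all of them lower in TEM4-18: CALB1, DNAJC15, CDH1, EHF, ESRP1, PI3, CYP1B1, TGFA, GATA2, SERPINB5, CD24 and ITGB8.

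TEM2-5 lay between PC-3 and TEM4-18 for many of these genes, for which a candidate explanation is a fixed share of PC-3 RNA in TEM2-5, that is a single position of TEM2-5 between the other lines (0 at TEM4-18 and 1 at PC-3, on linear signals). Over genes changed at least 8-fold between TEM4-18 and PC-3, the median position was 0.179 for 148 falling genes and 0.536 for 11 rising genes. The difference of -0.357 (95% bootstrap interval -0.491 to -0.136) argues against a single share for the whole pattern. At 4-fold or more it was -0.218 (interval -0.264 to -0.149). Each position is the mean over the 2 TEM2-5 arrays. The middle 50% of positions at 8-fold spanned 3.35 times the middle 50% of 1 array's deviations from that mean. Independent noise of the 2 TEM2-5 arrays gives their mean and 1 array's deviation from it the same spread. The ratio of 3.35 was over the limit of 2 set for this test and goes against a single share as well. Noise of the PC-3 and TEM4-18 arrays widens the positions too and is not in the deviations. Array scaling is argued against by quantile normalization, after which the median position was still 0.172 (interval 0.155 to 0.195) for falling and 0.535 (0.319 to 0.667) for rising genes. For falling genes alone the middle 50% lay between 0.131 and 0.255 and spanned 2.67 times that of 1 array's deviations from the mean. The 95% bootstrap interval, 1.84 to 3.90, includes the limit of 2. It lies above 1, the ratio that noise of the TEM2-5 arrays alone would give, but noise of the other arrays widens these positions too. A smaller share of PC-3-like cells therefore stays open for these genes. Single genes chosen after their values were seen lay apart on both TEM2-5 arrays. Examples were CBLC (-0.0106 and 0.0109), CDH1 (0.168 and 0.165), GATA2 (0.408 and 0.396) and BCL11B (0.907 and 1.03), which a single share gives only with unequal array responses. Such responses, several kinds of cells in TEM2-5 and a difference between the isolates in every cell stay open too.

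KDR and ENG rose in both TEM lines, which were isolated through an endothelial layer. ESAM (1.05) and ROBO4 (0.76) of the same list, chosen after their values were seen, rose on the mean of both lines too. Carried-over endothelial RNA would raise the abundant endothelial markers together. The median log2 fold change of the 34 markers other than KDR and ENG was -0.16 (95% bootstrap interval -0.27 to -0.09), which argues against it. Of all 36 markers, 15 passed the filter, and the others had low, noisy signals. The median therefore says little about a small share of such RNA. PECAM1, CDH5 and VWF, abundant in endothelial cells, were at -0.16, 0.094 and -0.22, and were chosen after their values were seen. A change of expression in the tumour cells themselves stays open and was not tested.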

How the results depend on the processing

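All alternatives were chosen before the data were examined. Without the mean-variance trend the counts were 5360 (TEM4-18 against PC-3), 2320 (TEM2-5 against PC-3), 5461 (mean of both), 125 (between the lines) and 2131 (shared). At 2-fold or more they were 2681, 1468, 2136, 301 and 1289 by construction. Leaving out each array in turn, which leaves a line with a single array assumed to vary like the others, gave 5980 to 7747, 2825 to 5135, 5772 to 7621, 218 to 550 and 2621 to 4037. With no filter, 300.0 probe sets differed between the lines. Other pseudocounts, filters, quantile normalization, a robust variance model and 2-group fits kept all other counts within 1.5 times. The titles share replicate numbers. Deviations of same-numbered arrays correlated at only 0.0625, 0.0804 and 0.0978 across probe sets, which leaves out shifts common to all probe sets. Replicate 1 had the higher median signal in each line (317 against 282 in PC-3, 296 against 267 in TEM4-18, 310 against 281 in TEM2-5). It was also higher in each on the second principal component, which held 13.0% of the variance (12.9 and -29.6, 2.39 and -33.6, 37.4 and 10.5). A replicate effect stays open, and the main fit had no term for it. With a replicate block the counts were 9445, 6429, 9717, 874 and 5636. Leaving out PC-3 replicate 1 or 2 moved the share of higher calls in TEM2-5 from 53.3% to 60.3% or 59.9%.

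Camera called 0 lists in all 4 contrasts with an estimated correlation (5, 4, 5 and 5 at an unadjusted p under 0.05), against 11, 10, 11 and 12 at the preset one; fry called 18, 13, 18 and 6. For keratins and receptor tyrosine kinases in TEM4-18 against PC-3, the estimated correlations were -0.013 and -0.0066, below the preset 0.01. A higher correlation within the list therefore did not end these calls. For interferon-stimulated genes it was 0.261, above the preset. The cause of the other differences was not tested. FN1, mean of both TEM lines against PC-3, ranged from -0.054 to 0.14 when each array was left out, with the sign reversed without TEM4-18 replicate 1 and without TEM2-5 replicate 1, and it passed in no contrast. IL11, mean of both TEM lines against PC-3, was -0.0069 with all probe sets averaged. The cause was not tested. Of 115 named calls against PC-3, 94 held in every alternative run, and of 34 between the lines, 12. No signal over background was used here, so for genes near the 51.8 pseudocount the arrays limit the size of a fold change.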

Other observations

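The correlations of adjacent genes and of genes 5 positions apart, and the largest window median between same-line arrays, were chosen before those values were seen. Windows of neighbouring genes in the comparisons of lines were added afterwards. Correlations of genes 20 positions apart and of adjacent genes between same-line arrays were not among the chosen tests.

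Genes that neighbour each other on a chromosome tended to change together. Among windows of 40 neighbouring tested genes, the one from COPS3 to WSB1 had a median log2 fold change of -1.04 in TEM4-18, with 37 of 40 genes lower, and -0.87 in TEM2-5, with 36 lower. Windows started every 20 genes, so neighbouring windows share genes and their counts are not counts of separate regions. The window from HS3ST3B1 to EVPLL overlaps the first and had medians of -0.93 and -0.76. Higher medians were found from CCDC198 to CHURC1 (0.86 in TEM4-18 and 0.49 in TEM2-5), from ATL1 to NAA30 (0.81 and 0.65) and from NCEH1 to FAM131A (0.45 and 0.28). Of 645 windows, 26 in TEM4-18 and 18 in TEM2-5 had medians beyond bounds that the most extreme window passed in 2.5% of 1000 shuffles of gene order on each side (-0.37 and 0.28 in TEM4-18), and 17 did so in both lines in the same direction, 6 lower and 11 higher. Both lines share the PC-3 arrays, so the lines are not independent here. Between the lines 15 windows lay beyond the bounds, 8 higher in TEM4-18 and 7 lower. The largest medians were 0.36 from CDKN3 to PRKCH and 0.35 in the overlapping window from CCDC198 to CHURC1. The overlapping windows from FCF1 to CEP128 and from RBM25 to ANGEL1 were lower, by -0.33 and -0.30.

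A candidate explanation is a difference in gene copy number between PC-3 and the TEM lines, which is a hypothesis found and tested on the same data. Over genes with a log2 fold change under 1 in size, adjacent genes correlated at 0.114 in TEM4-18 against PC-3, above the highest of 1000 shuffles (0.0299), as this explanation needs. Shared probe sets or gene copies limited to adjacent genes are argued against by genes 5 positions apart, which still correlated at 0.0469 (highest shuffle 0.0273). Longer runs of gene copies stay open. The window from the histone genes H3C3 to H2AC17 was among those lower in TEM4-18 than in TEM2-5 (-0.24). Genes 20 positions apart correlated at 0.0199, inside the shuffles (highest 0.0261, 18 of 1000 as large). Array noise is argued against for the windows against PC-3, as the largest window median between same-line arrays was 0.20 in size, inside the bounds for both lines. It is not argued against for all windows between the lines, where the upper bound was 0.15. There the median was 0.15 from ST6GAL1 to PAK2 and 0.17 from POLR2H to XXYLT1. Adjacent genes also correlated between same-line arrays, at 0.0192 in PC-3, 0.0284 in TEM4-18 and 0.0405 in TEM2-5, lower than the 0.114 above. Regional control of transcription would give the same pattern, and no DNA data were used here. Whether PC-3 or the TEM lines changed, and whether both lines came from the same PC-3 subpopulation, stays untested.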
